A study of Caenorhabditis elegans with 2 samples.

How the data were processed

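Peak lists from 2 biological replicates of AHR-1-GFP ChIP-seq in late embryos were analysed, together with the list from both replicates pooled and the IDR list, each on builds ce10 and ce11, per the labels and the deposited file descriptions. Chromatin was sonicated, per the labels. The authors called regions in each replicate and in the pooled alignments against a control library, and derived the IDR list from these lists, per the deposited file descriptions. The control library and signal tracks were not analysed here. The aligner, the peak caller, their settings, the IDR threshold and the read depth are not given in the sources used here. The labels name ahr-1 as the antibody target, while their description states an antibody against GFP; the second was followed.

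Each region in the deposited lists carries a signal value and a −log10 q value, both the authors' own. The signal is on a separate scale in each list and was used only to rank and describe regions within a list. The 479 regions of the IDR list are the 479 regions of highest signal in the pooled list, so the list acts as a rank limit on the pooled regions. Most regions have a fixed width (444 bp in the pooled list, 450 bp in replicate 1 and 436 bp in replicate 2). Narrower ones, down to 111 bp in the pooled list, include the strongest peaks. Width was not used as a measure of the extent of binding. How reads mapping to several places were treated is not given in the sources used here, which bears on repeated genes such as those of tRNAs.

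The ce11 lists were combined with the Ensembl gene annotation and the RefSeq sequence of WBcel235, whose chromosome lengths and names fit the coordinates. The ce10 lists were used only for counts and overlaps within that build. Analyses were run in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Replicate overlap was measured between the 479 strongest regions of each replicate (at least 1 bp) against 10000 circular shifts along each chromosome. A coding gene counted as bound when an IDR summit lay between 1500 bp upstream and 500 bp downstream of the 5′ end of a coding transcript. Shares of summits near coding 5′ ends, and within 250 bp of tRNA or other small RNA genes, were set against 10000 circular shifts, and chromosome shares against 10000 draws of coding genes. Circular shifts keep the spacing of peaks but place them in closed and open chromatin alike.

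Motifs were counted within 100 bp of each summit on either strand. Control windows, 5 for each peak, had the same signed distance to the 5′ end of another coding gene and no IDR peak within 2000 bp, and Fisher's exact test compared the shares. Where a cell of a table was 0, 0.5 was added to each cell for the odds ratio. P-values for motifs, 6-mers, gene lists and RNA classes were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. In these tests the units are regions or genes, so the p-values do not measure variation between replicates. Identical tRNA genes counted as separate units, though they can share reads and sequence. Tests across tRNA genes therefore hold fewer independent units than genes, and their p-values may be too low. Wilson intervals at 95% cover counting error only. The motifs, gene lists, tests and the rule for named genes were fixed before the data were examined. The rule took the 10 peaks of highest signal with the nearest coding gene and a divergent partner, then ahr-1, aha-1 and unc-119. It also took the 4 bound members of highest signal in each list that passed, and up to 3 bound members of the AHR and HIF, URX-type, touch and PVD, GABA, P450, UDP-glycosyltransferase and glutathione S-transferase lists. Other named genes, such as those of chaperones, were chosen after their values were seen.

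The tests were checked on simulated data. With random positions in place of the 479 peaks the promoter test made calls in 5% of sets, and with control windows in place of peaks the GCGTG test did so in 5%. Those mock peaks came from the control windows themselves. The check therefore does not cover the difference in GC and CpG content between summit windows and controls. With 60% of positions planted at 5′ ends, and with a site planted in 30% of windows, calls were made in 100% of sets. Random bound genes gave a call for any gene list in 2% of sets, and ribosomal protein genes drawn at 4 times the rate of others were called in 52%. A random second list gave a call of replicate overlap in 6% of sets. The alternatives were other windows, other backgrounds, the ce10 lists, the stronger 0.5 of the peaks, and the strongest regions of each replicate alone. Alternatives without peaks near tRNA or other small RNA genes, and with windows matched on GC content and the number of CpG, were added after seeing the data.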

Results

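The data are chromatin immunoprecipitation sequencing (ChIP-seq) peak lists for AHR-1, the *C. elegans* member of the aryl hydrocarbon receptor family of bHLH-PAS transcription factors. The worms carried a transgene encoding AHR-1 with a C-terminal GFP and FLAG tag in a strain mutant for the neuronal gene unc-119, and chromatin was precipitated with an antibody against GFP. Hermaphrodite late embryos were collected 3.5 h after synchronization by egg bleaching. There was 1 group, with 2 biological replicates, so no conditions were compared and the questions addressed here are where the tagged protein was found and how well the replicates matched. The list of replicate 1 held 22949 regions and that of replicate 2 held 23313, both before thresholding. The list from both replicates pooled held 13858 regions, of which 479 formed the list thresholded by IDR, a method based on how alike regions rank in replicates. These are the 479 of highest signal in the pooled list. Read depth was not given in the sources used here, and positions are on build ce11 (WBcel235), counted from 1.

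The IDR peaks had signal values from 69.2 to 1026 (median 98.2), as the authors' caller gave them, and 445 of the 479 were 444 bp wide. Their −log10 q values ran from 1.94 to 2.87. The strongest peak lay on chromosome III at 8043776 to 8044155, between genes, 526 bp upstream of K12H4.5 and 1086 bp upstream of the divergent gene K12H4.6. The next, with a signal of 546.3, lay at III 3499876 to 3500170 in an intron of M01F1.8, 966 bp upstream of M01F1.9. Another 4 of the 10 strongest peaks lay between divergent protein-coding genes. That at IV 390361 to 390592 had a signal of 334.0 and lay 8 bp upstream of ears-2, which encodes a glutamyl-tRNA synthetase, and 84 bp upstream of uncp-18. That at IV 17087531 to 17087751 had a signal of 309.4 and lay 187 bp upstream of snx-13, a sorting nexin gene, and 424 bp upstream of snr-1, which encodes a spliceosomal Sm protein. That at IV 1745713 to 1745851 had a signal of 292.0 and lay 227 bp upstream of Y41D4A.4 and 271 bp upstream of Y41D4A.6. The peak at III 10461187 to 10461445, with a signal of 331.5, lay 64 bp upstream of atx-2, the ataxin-2 gene, and 774 bp upstream of ecps-1. The reference sequence at its summit, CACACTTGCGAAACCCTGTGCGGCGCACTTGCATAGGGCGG, spans 20 bp to each side of position 10461325.

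The remaining 4 of the 10 strongest peaks lay at snoRNA genes, which encode small RNAs that guide the modification of ribosomal RNA. The peak at V 12303494 to 12303760 (signal 466.6) lay within frm-7, at the snoRNA genes C51F7.3 and C51F7.4, and its nearest coding 5′ end was that of F55C5.17, 1095 bp away. The peak at II 11960683 to 11960950 (signal 372.8) was intergenic at the snoRNA gene W03C9.9, with W03C9.1 as the nearest gene by 5′ end, 1324 bp away. The peak at V 15873877 to 15874078 (signal 321.0) was intergenic at the snoRNA gene T06C12.16, 1407 bp downstream of the 5′ end of the chemoreceptor gene str-56. The peak at V 8500436 to 8500647 (signal 290.1) lay in an intron of the peroxidasin gene pxn-1, 5648 bp from its 5′ end, at the snoRNA gene ZK994.7.

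The replicates shared most of their strongest regions. Of the 479 strongest regions of replicate 1, 329 overlapped one of the 479 strongest of replicate 2 by at least 1 bp, or 68.7% (95% Wilson interval 64.4 to 72.7%). Circular shifts of one list against the other gave a mean of 0.430% and at most 12.5% (one-sided permutation p = 0.0001, the smallest that 10000 shifts can give). Every IDR peak overlapped a region in both replicate lists, 322 of the 479 were among the strongest 479 of both, and 16 were among them in neither. Across the IDR peaks, the signals in the replicates had a Spearman rho of 0.638 (bootstrap 95% interval 0.569 to 0.697); this is across regions, which are not independent replicates. The IDR peaks are the strongest of the pooled list, which holds both replicates. Values across them therefore describe that list and are no separate measure of how well the replicates match. The top peak, at K12H4.5, ranked 1 in both replicates. The worst rank of an IDR peak was 8200 among the 22949 regions of replicate 1 and 16403 among the 23313 of replicate 2.

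The peaks lay mainly near 5′ ends of protein-coding genes, with most summits upstream of the nearest one. The summits of 334 of the 479 (69.7%, Wilson interval 65.5 to 73.7%) fell between 1500 bp upstream and 500 bp downstream of a coding 5′ end, against 38.9% ± 2.33 (SD over 10000 circular shifts; two-sided permutation p = 0.0002, the smallest they can give). The nearest coding 5′ end was a median of 398 bp away, and 341 summits lay upstream of it, a count that was not set against the shifts. By annotation, 272 summits (56.8%) were intergenic against 35.8% after shifting, 109 (22.8%) were in exons of non-coding genes against 1.23%, 74 (15.4%) in introns against 33.6%, 11 (2.30%) in coding sequence against 24.5% and 3 (0.626%) in 3′ UTRs against 3.39%. These 5 classes differed from the shifts with Benjamini-Hochberg adjusted permutation p = 0.00048 or lower. In 5′ UTRs lay 10 summits (2.09%), against 1.41% (adjusted permutation p = 0.289). The window counted 516 of 19973 coding genes as bound. A narrower one, from 500 bp upstream to 200 bp downstream, counted 324.

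Peaks were concentrated at tRNA and snoRNA genes. A summit lay within 250 bp of a tRNA gene at 99 of 479 peaks (20.7%, Wilson interval 17.3 to 24.5%), against a mean of 0.341% and at most 2.09% after shifting (permutation p = 0.0002). Of 612 annotated tRNA genes, 107 (17.5%) had an IDR summit. Other small RNA genes (snoRNA, snRNA, miRNA and rRNA) accounted for 53 more peaks (11.1%), against 0.443% (permutation p = 0.0002). Among the 239 strongest peaks their share was 17.2%. By class these were 45 peaks at snoRNA genes, 6 at genes of snRNAs, the RNAs of the spliceosome, and 2 at miRNA genes. The miRNA number did not differ from the shifts (adjusted permutation p = 0.389), and no peak lay at the 20 rRNA genes. The largest share was near genes annotated only as ncRNA, with 128 peaks (26.7% against 4.07%, adjusted permutation p = 0.0005). Of the 327 peaks near neither a tRNA nor another small RNA gene, 42 lay near an ncRNA gene. Peaks were fewer than after shifting at genes of piRNAs, small germline RNAs, with 1 peak near 15363 genes (0.209% against 3.06%, adjusted permutation p = 0.0008), and at pseudogenes, with 7 peaks (1.46% against 3.79%, adjusted permutation p = 0.012). No mock or untagged precipitation was analysed here, so these shares were not set against the background of the assay.

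**Figure D1:**
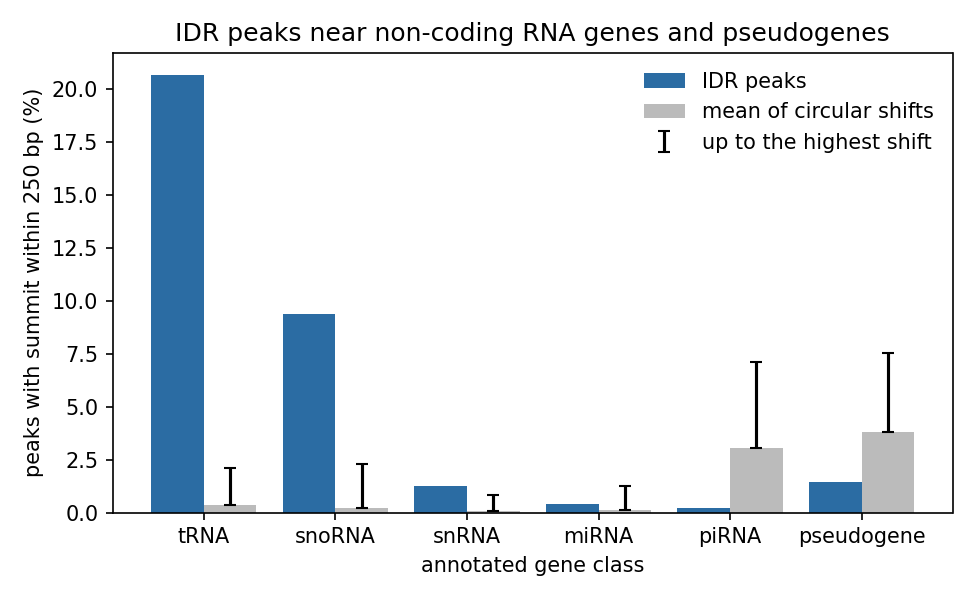
Share of the 479 IDR peaks with a summit within 250 bp of a gene of each class (blue bars, %), beside the mean of 10000 circular shifts (grey bars; the line runs up to the highest shift). tRNA and snoRNA genes stand far above the shifts, at 20.7% and 9.39% of peaks; genes annotated only as ncRNA are not drawn.

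The X chromosome held 95 of the 479 peaks (19.8%), more than its 13.7% of coding genes (two-sided permutation p = 0.0006 from 10000 draws of genes). Of those 95, 57 were at tRNA genes, and X carries 276 of the 612 tRNA genes (45.1%). None of the 53 peaks at other small RNA genes was on X. Without the peaks near tRNA genes, a choice made after seeing the data, the X share was 10%, below that of genes (38 of 380, permutation p = 0.0386). Without those near any small RNA gene it was 11.6% (permutation p = 0.301). The middle of the chromosomes, from the first to the last quartile of their length, held 265 peaks (55.3%), against 55.3% of coding genes (permutation p = 1).

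**Figure D2:**
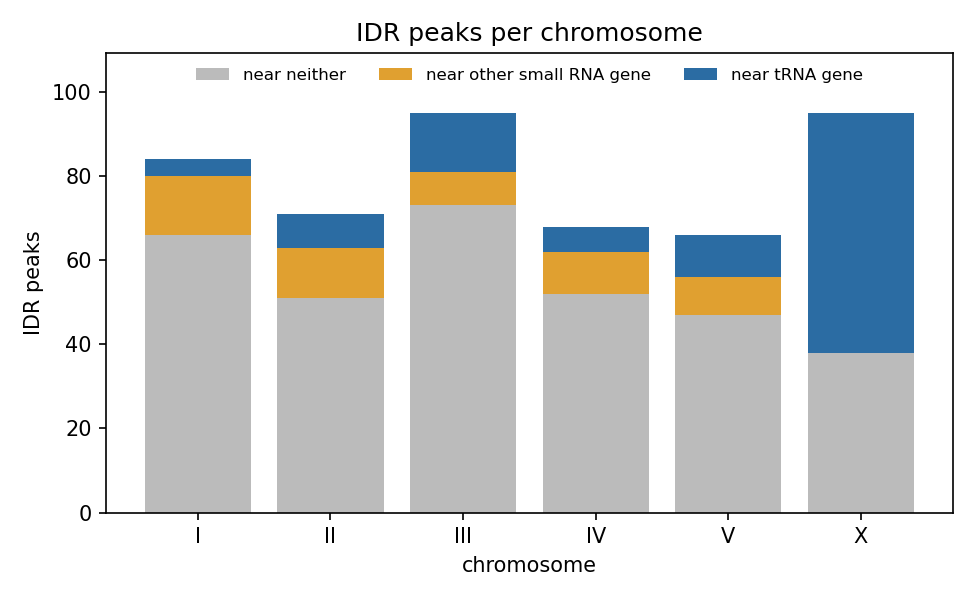
Number of IDR peaks on each chromosome, stacked by whether the summit lay within 250 bp of a tRNA gene (blue), of another small RNA gene (orange) or of neither (grey). On X, 57 of 95 peaks are at tRNA genes, against 4 of 84 on chromosome I.

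The core of the xenobiotic response element, GCGTG, which AHR and its partner ARNT bind, was frequent at the summits. It occurred on either strand within 100 bp of 193 of 479 summits (40.3%), against 266 of 2391 control windows (11.1%) placed at the same distance from other coding genes. The peaks of rank 1 and 2 by signal had no GCGTG there. The log2 odds ratio was 2.43 ± 0.16 (SE; Fisher's exact test, two-sided, p = 4.65e-47). It was at 46 of 99 peaks near tRNA genes (46.5%, against 12.9% of their control windows), 20 of 53 near other small RNA genes (37.7% against 8.75%) and 127 of 327 near neither (38.8% against 12.4%). The controls lie at coding genes, so they do not show what tRNA genes hold without binding. Within 100 bp of tRNA genes GCGTG was at 34.4% of the 294 with no pooled region and 43.0% of the 107 with an IDR summit (Fisher's exact test, p = 0.128), a comparison chosen after seeing the data. The longer form TNGCGTG was at 47 summits (9.81% against 3.09%, log2 odds ratio 1.77 ± 0.28). Each TNGCGTG contains GCGTG, so it is no separate evidence. It was in 47 of the 193 summit windows with GCGTG and in 74 of the 266 such control windows. Summit windows were richer in G and C, at 43.7% against 34.9%. With control windows matched on GC content as well, the log2 odds ratio of GCGTG was 1.38 ± 0.15 and that of TNGCGTG 0.99 ± 0.26. With controls matched on GC and CpG content, a background chosen after seeing the data, they were 1.17 ± 0.15 and 0.63 ± 0.25.

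**Figure D3:**
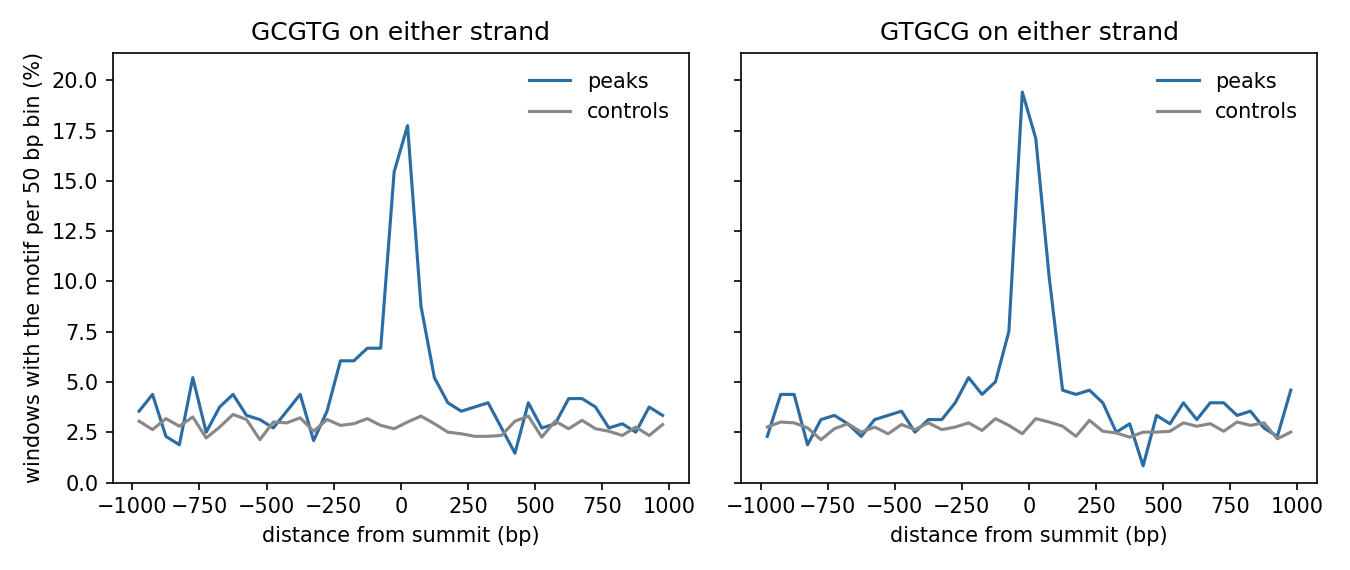
Share of windows (%) with GCGTG (left) or GTGCG (right) in each 50 bp bin from 1000 bp before to 1000 bp after the summit (x axis, bp), in IDR peaks (blue) and distance-matched control windows (grey). GCGTG reaches 17.7% of peaks just after the summit against 3.01% of controls; GTGCG was added after seeing the data.

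Of the 15 motifs fixed in advance, 8 passed an adjusted p of 0.05 (Fisher's exact test, Benjamini-Hochberg). Besides both forms of the response element, the related HIF core RCGTG (log2 odds ratio 1.53 ± 0.15), an E2F site (1.29 ± 0.23) and the GA repeat GAGAGA (1.21 ± 0.18) were more frequent at summits. RCGTG includes every GCGTG: of the 243 summits and 628 control windows with RCGTG, 193 and 266 held GCGTG. Its other form, ACGTG, was not tested alone, so RCGTG is no separate evidence of a HIF site. In a split by class of peak chosen after seeing the data, GAGAGA was highest near tRNA genes. It was there at 36.4% of peaks against 9.49% of their control windows (log2 odds ratio 2.45 ± 0.37). Near other small RNA genes its log2 odds ratio was 0.55 ± 0.57, and near neither 0.86 ± 0.22. The values of RCGTG, E2F and GAGAGA were lower against controls closer in composition. RCGTG was at 0.75 ± 0.15 with GC matching and 0.48 ± 0.15 with GC and CpG matching, and GAGAGA at 0.52 ± 0.17 and 0.68 ± 0.18, all still called. Of the 903 GC-matched control windows with RCGTG, 490 held GCGTG, against 193 of the 243 summits. The call of RCGTG thus does not speak for ACGTG. The E2F site was at 0.54 ± 0.22 with GC matching, and at -0.041 ± 0.22 with GC and CpG matching, where it was no longer called (Fisher's exact test, adjusted p = 1). It was at 0.72 ± 0.19 within 250 bp of the summit. The GATA site was less frequent (21.3% against 39.3%, log2 odds ratio -1.26 ± 0.17), as were the splice acceptor TTTCAG (-1.28 ± 0.18) and a run of T (-1.19 ± 0.22). With GC matching, and with GC and CpG matching, GATA was at -0.80 ± 0.17 and -0.57 ± 0.18 and TTTCAG at -0.61 ± 0.19 and -0.73 ± 0.19, all still called. Within 250 bp of the summit they were at -0.61 ± 0.15 and -0.54 ± 0.15. The run of T was at 0.0091 ± 0.22 with GC matching, 0.020 ± 0.22 with GC and CpG matching and -0.32 ± 0.15 within 250 bp, not called in any of these, and at -2.31 ± 0.40 within 50 bp. The E-boxes CACGTG (-0.23 ± 0.40) and CANNTG (-0.17 ± 0.14) did not pass with the main background. CANNTG was less frequent with GC matching, an alternative fixed in advance (-0.52 ± 0.14, Fisher's exact test, adjusted p = 0.00117), and CACGTG with GC and CpG matching (-0.90 ± 0.39, adjusted p = 0.0306). In a search of all 2080 6-mers, 557 were more and 365 less frequent at summits at an adjusted p of 0.05; with GC matching these were 281 and 284. The lowest p belonged to GCGCAC, at 97 summits (20.3%, log2 odds ratio 3.12 ± 0.24, Fisher's exact test, adjusted p = 1.11e-33). It contains GTGCG, another order of the letters of GCGTG, on its other strand. Next was CACGCG, which contains the response element core on its other strand, at 76 summits (3.58 ± 0.30). With GC matching GCGCAC still had the lowest p (2.10 ± 0.21), while CACGCG ranked 13 by p (1.71 ± 0.22). Among the 327 peaks away from small RNA genes CACGCG ranked 15 (2.77 ± 0.30). Some 6-mers followed the class of peak, a split chosen after seeing the data. GTTCGA, of rank 2 by p with GC matching (1.82 ± 0.19), was at 72 of 99 peaks near tRNA genes (72.7% against 6.87% of their control windows). It was at 19 of 53 near other small RNA genes (35.8% against 6.46%). Near neither it was at 26 of 327 (7.95% against 6.67%, log2 odds ratio 0.27 ± 0.33).

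Of the 21 gene lists fixed before the data were examined, the cytosolic ribosomal proteins alone passed the adjusted threshold. Of their 78 genes, 11 were bound (14.1%), against 505 of 19895 other genes (2.54%), a log2 odds ratio of 2.66 ± 0.47 (Fisher's exact test, adjusted p = 0.000105). The strongest of these peaks lay 269 bp upstream of rpl-3 (III 3867512 to 3867660, signal 209.5), 560 bp upstream of rps-24 (IV 385105 to 385548, signal 202.6), 343 bp upstream of rpl-15 (IV 654829 to 654949, signal 179.1) and 449 bp upstream of rpl-35 (III 7854463 to 7854906, signal 141.9), all intergenic and with GCGTG within 100 bp of the summit. When each summit counted only for its nearest coding gene, 7 of the 78 ribosomal protein genes were bound (8.97%). The log2 odds ratio was then 2.08 ± 0.58 (Fisher's exact test, adjusted p = 0.044). Against circular shifts of the peaks, with a mean of 0.806 bound genes, the 11 had an adjusted permutation p = 0.0042. Heat shock and stress genes had 3 of 32 members bound (Fisher's exact test, raw p = 0.0489, adjusted p = 0.513). These were the chaperone genes hsp-60, hsp-1 and hsp-3.

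No list of genes of AHR-1 biology or of detoxification passed the adjusted threshold (Fisher's exact test, adjusted p = 1 for each). None was bound among the 10 genes of the AHR and HIF pathway, the 19 of touch and PVD neurons, the 11 of GABA neurons or the 74 cytochrome P450 genes. Of 16 genes in the list made for the oxygen-sensing URX-type neurons, 1 was bound (6.25%). It was gcy-33, a soluble guanylyl cyclase gene, 394 bp from a peak at V 12001969 to 12002412 (signal 162.5) that lay on a tRNA gene. Whether each listed gene is expressed in these neurons was not examined here. Of 67 UDP-glycosyltransferase genes, 1 was bound (1.49%), ugt-50, with a peak in an intron at X 12691899 to 12692342 (signal 74.5). Of 44 glutathione S-transferase genes, 2 were bound (4.55%), gst-26 and gst-27, through 1 peak at II 15165799 to 15166242 (signal 112.5) on the snoRNA gene Y53F4B.48. Histone genes had 4 of 72 members bound (Fisher's exact test, adjusted p = 0.81), nuclear hormone receptors 3 of 269 (adjusted p = 0.898) and collagens 3 of 156 (adjusted p = 1). No gene was bound in the lists of pan-neuronal, ciliated neuron, intestine, body muscle, epidermis, pharynx, germline, homeobox or bHLH genes (Fisher's exact test, adjusted p = 1 for each). The genome-wide rate was 2.58%, and with so few bound members in each list of this paragraph neither an excess nor a shortage was shown.

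ahr-1, aha-1 (the worm ARNT gene, on chromosome I) and unc-119 had no IDR peak. The strongest pooled region at ahr-1 (I 9522550 to 9531132) lay in coding sequence at 9527682 to 9528125, with a signal of 39.99 and rank 3048. That at aha-1 (10193925 to 10196997) had a signal of 33.4 and rank 6412, and that at unc-119 (III 10902641 to 10908935) was intronic with a signal of 35.5 and rank 5042. Within 20000 bp of ahr-1 the pooled list had 20 regions, percentile 99.8 among windows of the same size around coding genes (median 6). The corresponding values were 10 regions and percentile 87.0 at unc-119 (median 5). In the lists of the single replicates, ahr-1 was at percentile 96.1 in replicate 1 and 93.4 in replicate 2, the second below the 95th percentile used as the limit.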

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

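The tests of regions below the IDR threshold at tRNA genes, of identical copies on X and autosomes apart, of tRNA genes with no identical copy, of GCGTG at tRNA genes, of windows matched on CpG and of windows without GTGCG were chosen after the result was seen. The tests of identical copies over all tRNA genes, of letter orders and of transgene copies were chosen before. The design has 1 group, so no biological explanation was tested by a comparison of groups.

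Among the 13379 pooled regions below the IDR threshold, which the report does not use for this purpose, 232 had a summit within 250 bp of a tRNA gene, against a mean of 42.7 and at most 66 in 1000 circular shifts. In all, 318 of the 612 tRNA genes had a pooled region, against 107 with an IDR peak. This drew attention because the signal at tRNA genes extends beyond the thresholded list.

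Reads shared between identical tRNA genes could place peaks at several copies. Of 469 tRNA genes with an identical copy, 90 had an IDR summit (19.2%), against 17 of 143 without (11.9%), a log2 odds ratio of 0.82 ± 0.41 (SE; Fisher's exact test, p = 0.0448), in the direction that shared reads predict. The value was 1.33 ± 0.62 on X and 0.21 ± 0.56 on the autosomes, a difference that was not tested. Identical copies were counted as separate genes, though they can share reads, so the p-value over all tRNA genes may be too low. Shared reads between identical copies do not account for the 17 peaks at tRNA genes with no identical copy, against 0.356 after shifting (permutation p = 0.0002), though near-identical copies were not examined. GCGTG was within 100 bp of 46 of the 107 tRNA genes with an IDR summit (43.0%) and 101 of the 294 with no pooled region (34.4%), a log2 odds ratio of 0.53 ± 0.33 (Fisher's exact test, p = 0.128), so whether this site marks the bound tRNA genes stays open, as does non-specific recovery of tRNA genes by the assay.

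The frequency of GCGTG at summits may come from base composition. A test fixed beforehand compared it with the other orders of the same letters, of which composition alone would put some as high. GTGCG was higher, so that GCGTG differed from the highest other order by -0.21 on the log2 scale and ranked 2 of 20, the outcome that had been assigned to composition. That test cannot separate composition from a second motif. A later value, over all peaks together, argues against GC and CpG content as the whole cause. With controls matched on both, GCGTG was still more frequent (log2 odds ratio 1.17 ± 0.15, down from 2.43), while the median of the 20 orders fell to 0.11. GTGCG stayed higher there (1.36 ± 0.15), so GCGTG again ranked 2, and the next order, CCACG, was at 0.71 ± 0.15. The lowest order, CCGAC, was at -0.86 ± 0.19, so matched orders still differed among themselves. Matching was not run without the peaks at tRNA genes. GCGTG was within 100 bp of 34.4% of tRNA genes with no pooled region, so the matched value of GCGTG cannot separate tRNA gene sequence from binding. Among windows without GTGCG, with the main controls and no GC or CpG matching, the log2 odds ratio of GCGTG was 2.29 ± 0.21. GTGCG in the same windows thus does not carry the main enrichment. With matched controls this was not tested.

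Extra copies of the transgene could raise the number of regions at ahr-1 and unc-119. In the pooled list the number exceeded the 95th percentile at ahr-1 (99.8) and not at unc-119 (87.0), so the 2 loci came out on opposite sides of the test, which leaves this open. In replicate 2 alone ahr-1 did not exceed it either (93.4).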

How the results depend on the processing

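Replicate overlap, rank agreement, promoter share, tRNA and other small RNA shares, GCGTG enrichment and the numbers of gene lists and motifs called kept their direction and call, or, for counts, stayed within 1.5 times, under every alternative run for them. Replicate overlap ranged from 53.1% (2 times as many regions) to 76.6% (the stronger 239), and the log2 odds ratio of GCGTG from 1.17 (GC and CpG matching) to 2.77 (within 50 bp). The share at other small RNA genes rose from 11.1% to 17.2% in the 239 strongest peaks. Changes of call or direction in other results and in single motifs follow, with changes by over 1.5 times in called motifs, and the cause was not tested except where named. Alternatives without small RNA peaks, or matched on CpG, were added after seeing the data. The X share turned from above to below that of genes without peaks near tRNA genes (10%) or any small RNA gene (11.6%), because 57 of the 95 peaks on X are at tRNA genes. The 557 enriched 6-mers fell to 365 in the 239 strongest peaks, where fewer windows were tested, with 198 depleted in place of 365. They fell to 371 without small RNA peaks and to 281 with GC matching. The 6-mer CACGCG, of rank 2 by p (log2 odds ratio 3.58), ranked 13 with GC matching (1.71) and 15 without small RNA peaks (2.77). Single motifs are given as log2 odds ratios. TNGCGTG and RCGTG share windows with GCGTG and were not tested apart from it. With GC matching, then GC and CpG matching, TNGCGTG went from 1.77 to 0.99 and 0.63, RCGTG from 1.53 to 0.75 and 0.48, GAGAGA from 1.21 to 0.52 and 0.68, GATA from -1.26 to -0.80 and -0.57 and TTTCAG from -1.28 to -0.61 and -0.73, all still called. The run of T went from -1.19 to 0.0091 and 0.020, and the E2F site from 1.29 to 0.54 and -0.041, where the run of T in both and E2F in the second were not called. Within 250 bp, GATA was at -0.61, TTTCAG at -0.54, E2F at 0.72 and the run of T at -0.32, the last not called; within 50 bp the run of T was at -2.31. Motifs called as less frequent only under alternatives were CANNTG (-0.52 with GC matching, -0.40 without small RNA peaks), CACGTG (-0.90 with GC and CpG matching), the homeodomain site (-0.81 and -0.69 in replicates 1 and 2 alone, -1.03 within 50 bp) and the heat shock element (-1.01 within 50 bp). The forkhead site was called as more frequent with GC and CpG matching (0.36). Values of motifs and gene lists that were called neither in the main analysis nor under the alternative also moved, some across 0, and are not listed. The ahr-1 percentile ranged from 93.4 to 96.1 in the lists of single replicates, so it fell below the 95th percentile in replicate 2 alone. No paired analysis was possible because there is 1 group. Read depth is unknown, which limits how regions below the threshold can be read.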

Other observations

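The tests of GTGCG, of peaks away from small RNA genes, of 6-mers by class of peak, of gene families by symbol, of sets of identical tRNA genes and of tRNA genes by chromosome were chosen after seeing the data.

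At summits away from small RNA genes, GTGCG had the highest odds ratio of the 20 orders of the letters of the response element core. It was within 100 bp of 155 of these 327 summits (47.4%, against 11.5% of control windows, log2 odds ratio 2.79 ± 0.20). GCGTG was at 127 (38.8%) and the HIF core RCGTG, a less specific pattern that includes GCGTG, at 162 (49.5% against 26.9%). Of the 200 of these peaks without GCGTG, 83 had GTGCG (41.5% against 9.36%, log2 odds ratio 2.78 ± 0.24). Over all 479 peaks the log2 odds ratio of GTGCG was 2.64 ± 0.16, which fell to 1.69 ± 0.15 with GC matching and 1.36 ± 0.15 with GC and CpG matching. The 6-mer of lowest p at the 327 peaks was GCGCAC, at 76 summits. It contains GTGCG on its other strand, so it is no separate evidence. Other 6-mers of higher p were at more summits, such as GCGAAA at 109. Of the 327 peaks, 272 (83.2%) lay in the window around coding 5′ ends.

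tRNA genes on X had an IDR summit more often than those on autosomes, 64 of 276 (23.2%) against 43 of 336 (12.8%; Fisher's exact test, p = 0.000885). The excess was seen in genes with an identical copy (26.0% against 13.2%, log2 odds ratio 1.21 ± 0.35, exact p = 0.000603) and not in those without, with 7 of 57 against 10 of 86 (0.089 ± 0.76, exact p = 1). Whether the 2 kinds of gene differ in this was not tested. The strongest tRNA peak, ranked 15 with a signal of 256.6, lay at X 13665487 to 13665637 on a gene with no identical copy (13665555 to 13665673), and the 5 strongest tRNA peaks were all on X. Among the 20 sets of at least 10 identical tRNA genes, none differed from the other tRNA genes after adjustment. The lowest p was that of a set of 15 genes with 7 bound (Fisher's exact test, adjusted p = 0.157).

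Of 175 gene families of at least 10 members grouped by symbol, none passed an adjusted p of 0.05. The lowest were cdc genes (4 of 16 bound), rps (5 of 31), sec (4 of 19) and rpl (6 of 47), each with an adjusted p of 0.0552. The str chemoreceptor family had 0 of 193 bound (Fisher's exact test, adjusted p = 0.235).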
